A study of Mus musculus with 12 samples.

How the data were processed

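Duodenal segments from mice of strain 129 were profiled at postnatal days 15 and 30, in wild type animals and in animals with Onecut2 ablated. There were 3 arrays in each of 4 groups, 12 in all. Per the labels, each array held total RNA pooled from 5 to 8 mice of mixed sex, extracted with Trizol, and 5.5 micrograms were labelled as biotinylated cRNA. The replicates are separate pools of animals, so the spread between arrays combines differences between pools with array noise, and it is smaller than the spread between single mice would be.

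The deposited values are log2 expression values per feature of a mouse whole-transcript gene array. Per the submitters' processing notes, they were made with RMA in Affymetrix Expression Console version 1.1, a method that corrects background, normalizes quantiles between arrays and summarises the probes of each feature on the log2 scale. The log base is not written beside the values and was taken as 2 from that method and from their range. Quantile normalization forces the arrays onto nearly one distribution, so a change shared by most genes would be removed. Array signals saturate at the top and flatten near background, so folds of very bright and of very dim genes are understated. For arrays, the number of pools limits the precision.

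The table held 35557 features. Of these, 21789 were paired with exactly 1 gene symbol, 1621 with several and 12147 with no listed gene. Only features with 1 symbol were tested, and where a gene had more than 1 (999 genes) the feature with the highest mean over the 12 arrays was used, which left 19938 genes. Entrez identifiers were matched to a RefSeq table of assembly GRCm38.p6, which held 21698 of the 1-symbol features and updated 0 symbols. That table served for names and chromosome only, since the genome build behind the array annotation is not given in the sources used here, and no coordinates are printed. No column of other samples was present. The highest correlation between any pair of arrays was 0.9978, and no array repeated another.

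Differences were tested with limma version 3.58.1 in R version 4.3.3. A linear model with 4 group means was fitted to all 12 arrays (8 residual degrees of freedom) and its variances were moderated with eBayes at default settings. The comparisons were day 30 against day 15 within each genotype, knockout against wild type at each age, the difference between those genotype effects, and the genotype effect averaged over both ages. P-values were adjusted by Benjamini-Hochberg within a comparison and called at 0.05. Errors of group means are SDs over 3 arrays, and errors of log2 fold changes are the moderated standard errors (SE).

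Before the data were examined, 38 lists of genes were written down for cell types, transport, metabolism and signalling of the small intestine and for tissues that a duodenal segment can carry along. Of their 540 entries, 484 were measured, and the other 56 were not measured here. There were 37 lists tested with camera from limma, two-sided, with its preset inter-gene correlation of 0.01, and again with the correlation estimated from the arrays. The list of Y-linked genes and Xist served as a check of the samples. In that check, Xist lay between 9.26 and 11.37 and Kdm5d between 6.82 and 8.17, so RNA of both sexes was present on each array in varying proportion. Reactome sets of 10 to 300 measured genes, 885 in all, were taken from the fgsea package version 1.28.0 and tested in the same way.

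A maturation score per array was the mean log2 value of the list of carbohydrate genes of the weaned gut minus that of the list of suckling-stage enterocyte genes. Groups were compared on it with an exact two-sided permutation test, whose smallest possible p with 3 against 3 arrays is 0.1. Named genes follow a rule fixed together with the lists. It takes Onecut2 and Ada, and the 8 largest rises and 8 largest falls among called genes whose 3 values in a group all lie above the 3 in the other, without predicted loci or antigen receptor segments. For the difference between genotype effects and the averaged effect, it takes 5 and 5. It adds up to 4 members with the smallest p of each list that was called or had at least 3 called members, and a set of leading list members that may be named with their values whether or not they passed. Glucagon at day 15 was named after its value there had been seen, to set it beside day 30.

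The code was tested on simulated arrays for the knockout comparison at day 15, over 19938 genes with the measured means and SDs. Of 67 genes changed by 0.5 on the log2 scale, 83.6% were called in the right direction. For changes of 1 the share was 97%, and for changes of 2 it was 100%. Among unchanged genes 10 were called, and the only list called was the list that had been shifted. The simulation drew genes independently, so it does not test the preset correlation.

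Alternatives fixed together with the lists were an intensity trend or robust moderation in eBayes, filters on dim features, all features, the mean over a gene's features, quantile normalization again, cyclic loess, only the arrays compared, the replicate number as a block, array weights, leaving out each array, and a list median in place of its mean. Added after seeing the data were a fit without 4 arrays and fits with the mean of a tissue list per array as a covariate. Scan dates and batches were not analysed here.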

Results

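Total RNA from mouse duodenum was measured at postnatal day 15, before weaning, and at day 30, after weaning, in wild type and Onecut2 knockout mice. Onecut2 encodes a transcription factor of the cut homeodomain family. Each of the 4 groups had 3 arrays, and 19938 genes were tested. The arrays had median log2 values between 7.20 and 7.26 over all features. The design compares ages within genotype and genotypes within age.

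The targeted gene was lower on each knockout array than on each wild type array. At day 15, Onecut2 averaged 9.64 ± 0.08 in wild type and 8.14 ± 0.05 in knockout (SD, n = 3), a log2 fold change of -1.50 (SE 0.06, limma adjusted p = 2.0e-08). At day 30 the means were 9.58 ± 0.07 and 8.22 ± 0.03, a log2 fold change of -1.36 (SE 0.06, limma adjusted p = 8.8e-08). Where the probes of this feature lie relative to the deleted part was not analysed here, so the value left in the knockout cannot be read as remaining transcript. The related genes Onecut1 and Onecut3 did not pass at either age, with log2 fold changes between -0.19 and 0.10. Ada, which encodes adenosine deaminase and carries a duodenal enhancer, had a log2 fold change of -0.44 at day 15 (SE 0.17, limma adjusted p = 0.22) and of -0.25 at day 30 (SE 0.17, limma adjusted p = 0.67), neither called. With age Ada rose by 0.67 in wild type and by 0.85 in knockout.

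**Figure D1:**
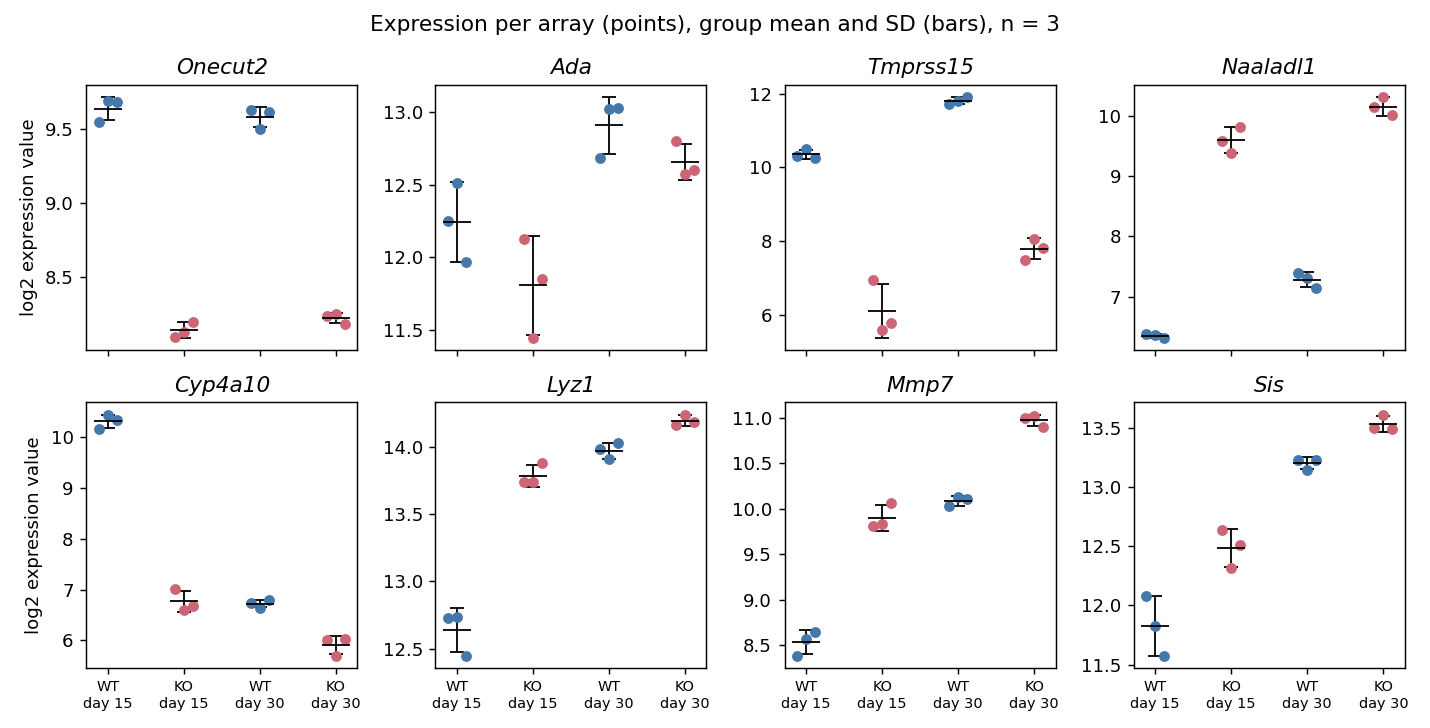
Log2 expression value per array (points) with the group mean and SD (bars) for 8 genes in wild type (WT, blue) and knockout (KO, red) at days 15 and 30, n = 3; each vertical axis has its own range. Onecut2 and Tmprss15 were lower and Naaladl1 and Mmp7 higher on each knockout array than on each wild type array of the same age, while the Ada values of the genotypes overlapped at both ages.

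The wild type duodenum changed broadly between day 15 and day 30. Genes of the suckling-stage enterocyte fell, among them the endocytic receptor gene Cubn (log2 fold change -4.60, SE 0.21). Other large falls were those of the phosphate transporter gene Slc34a2 (-5.14, SE 0.15) and of Cym (-4.45, SE 0.12), which encodes the milk-clotting protease of the stomach. Genes of plasma cells and cytotoxic lymphocytes rose, among them Jchain, which links immunoglobulin A (4.98, SE 0.30), Gzmb (3.30, SE 0.14) and Gzma (3.24, SE 0.18). Genes of cholesterol synthesis and of Paneth cells, the antimicrobial cells of the crypt base, rose as well, while all 18 genes of fatty acid oxidation fell, a list whose call was lost with an estimated correlation (adjusted p = 0.063).

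Of 19938 genes, 5849 passed, with 2455 higher and 3394 lower at day 30, and 196 and 214 of them changed at least 2-fold. Other large rises were those of Hsd17b6 (3.67), Cyp2b10 (3.45), B3galt5 (3.31), Smpdl3b (3.01) and Sult6b2 (2.98), with SEs of 0.07 to 0.25. Other large falls were those of Smcp (-5.34), Lect2 (-5.08), Cyp4a31 (-4.12), St3gal5 (-3.90) and Tdrp (-3.85), with SEs of 0.11 to 0.23.

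In the suckling-stage list, 11 of 12 measured members were lower, both over all genes and adjusted over the list alone, and the list fell (median -1.61, camera adjusted p = 5.6e-12, 0.026 with an estimated correlation). Its members included the endocytic adaptor gene Dab2 (-1.94) and the gluconeogenic enzymes Pck1 (-3.01) and Fbp1 (-1.97). Lactase, encoded by Lct, fell by 2.25. In the list of carbohydrate genes of the weaned gut, 6 of 10 members were higher (6 higher and 1 lower adjusted over the list alone), among them trehalase (Treh, 1.73), sucrase-isomaltase (Sis, 1.37) and the glucose transporter Slc5a1 (0.82). That list's call (median 0.83, camera adjusted p = 0.0021) was lost with an estimated correlation (adjusted p = 0.38).

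All 18 measured genes of cholesterol synthesis were higher, over all genes as adjusted over the list alone, with Cyp51 at 1.46, Idi1 at 1.45 and Sqle at 1.38 (camera adjusted p = 5.4e-17, 0.023 with an estimated correlation). All 18 genes of fatty acid oxidation and ketogenesis were lower by either adjustment, with Cyp4a10 at -3.59, Acot1 at -3.03 and Acot2 at -2.02 (camera adjusted p = 3.4e-15, but adjusted p = 0.063 with an estimated correlation). Of 21 fat absorption genes, 14 were lower and 4 higher (15 and 4 adjusted over the list alone), with Apoc3 at -2.20 and Plin2 at -1.85, and the list's adjusted p was 2.8e-06, or adjusted p = 0.12 with an estimated correlation. Brush-border peptidase and amino acid transport genes split, since Enpep (1.83), Mep1b (1.06) and Dpp4 (0.92) rose and Mep1a fell by 3.36. The calcium channel Trpv6 rose by 2.20 and the vitamin D receptor Vdr by 1.63, while that list was not called (camera adjusted p = 0.38).

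All 9 Paneth cell genes were higher by either adjustment (median 1.33, camera adjusted p = 2.7e-09, 0.045 with an estimated correlation), with Mmp7 at 1.56, Defa24 at 1.51 and Lyz1 at 1.33. Of 17 T cell and intraepithelial lymphocyte genes, 15 rose, including Cd3g (2.65) and Cd8a (1.91), and of 13 B and plasma cell genes, 10 rose, including Igha (4.30) and Ighm (3.08). Adjusted over the list alone the counts were again 15 and 10, and both lists were called with either correlation (adjusted p = 0.0011 and 0.013 with an estimated correlation). Of 14 antimicrobial and microbe-induced epithelial genes, 11 rose and 1 fell (11 and 2 adjusted over the list alone), with rises of the fucosyltransferase gene Fut2 (2.45), Reg3b (2.31), Reg3g (2.26) and Duox2 (2.22), and the list's adjusted p was 1.7e-04, or adjusted p = 0.12 with an estimated correlation. Of 18 enteroendocrine hormone and granule genes, 12 fell, among them Chga (-0.87), Gip (-0.86) and Sst (-0.80), and the list's adjusted p was 4.1e-06, or adjusted p = 0.13 with an estimated correlation. All 12 smooth muscle genes were lower, with Myh11 at -0.90 and Acta2 at -0.82 (camera adjusted p = 6.7e-10, but adjusted p = 0.12 with an estimated correlation), so muscle transcripts moved with age beside each of these groups. Xist, which marks female RNA in the mixed pools, fell by 1.03 (limma adjusted p = 0.030). In knockout it ran from 10.43 to 10.78 at day 15 and from 10.33 to 10.81 at day 30. No fit took account of sex, so wild type age calls and differences between ages may carry a part of this shift. In all, 18 of 37 lists were called with the preset correlation and 5 with an estimated one, and another split of the same 6 arrays also called 18 with the preset.

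The knockout duodenum changed with age in much the same genes as the wild type. There, 6178 genes passed (2753 higher, 3425 lower), and 4390 genes passed in both genotypes, with 1743 higher in both, 2636 lower in both and 11 in opposite directions. Independent lists of those sizes would share 339 higher and 583 lower genes. Across genes, which are not independent replicates, the age changes correlated with Pearson r = 0.89 and Spearman rho = 0.79, and the genotypes share no arrays. The same variance estimate of a gene enters its calls in both genotypes, which can raise the overlap above that of independent lists. It favours no direction, however, and only 11 shared genes went in opposite directions. Jchain (4.50), Sult6b2 (4.37) and Hsd17b6 (3.62) rose and Lect2 (-5.35), Smcp (-4.83) and Cubn (-4.52) fell in the knockout as well. Slc13a1 (3.48) and Bcl2l15 (3.20) were among its largest rises, and Hsd3b3 (-4.12), Mamdc4 (-4.01) and the interferon-induced gene Ifit2 (-3.94) among its largest falls. All 12 suckling-stage genes fell by either adjustment (median -1.79, camera adjusted p = 4.5e-14, 0.019 with an estimated correlation). Of 37 lists, 20 were called with the preset correlation and 3 with an estimated one, and another split of the same 6 arrays called 14 with the preset.

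The maturation score, high when carbohydrate genes of the weaned gut exceed suckling-stage genes, rose with age in both genotypes, by 2.41 in wild type and by 2.73 in knockout. At day 15 it averaged 0.64 ± 0.26 in wild type and 0.29 ± 0.19 in knockout (SD, n = 3, exact permutation p = 0.2), a difference of -0.348 that was -0.684 with the median of the list members in place of their mean. Part of that difference rests on wild type replicate 1, at 0.92 against 0.594 and 0.414 for replicates 2 and 3. At day 30 it averaged 3.05 ± 0.06 and 3.02 ± 0.09 (SD, n = 3, exact permutation p = 0.7). The smallest p that 3 against 3 arrays allow is 0.1, which is what each age comparison gave.

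**Figure D2:**
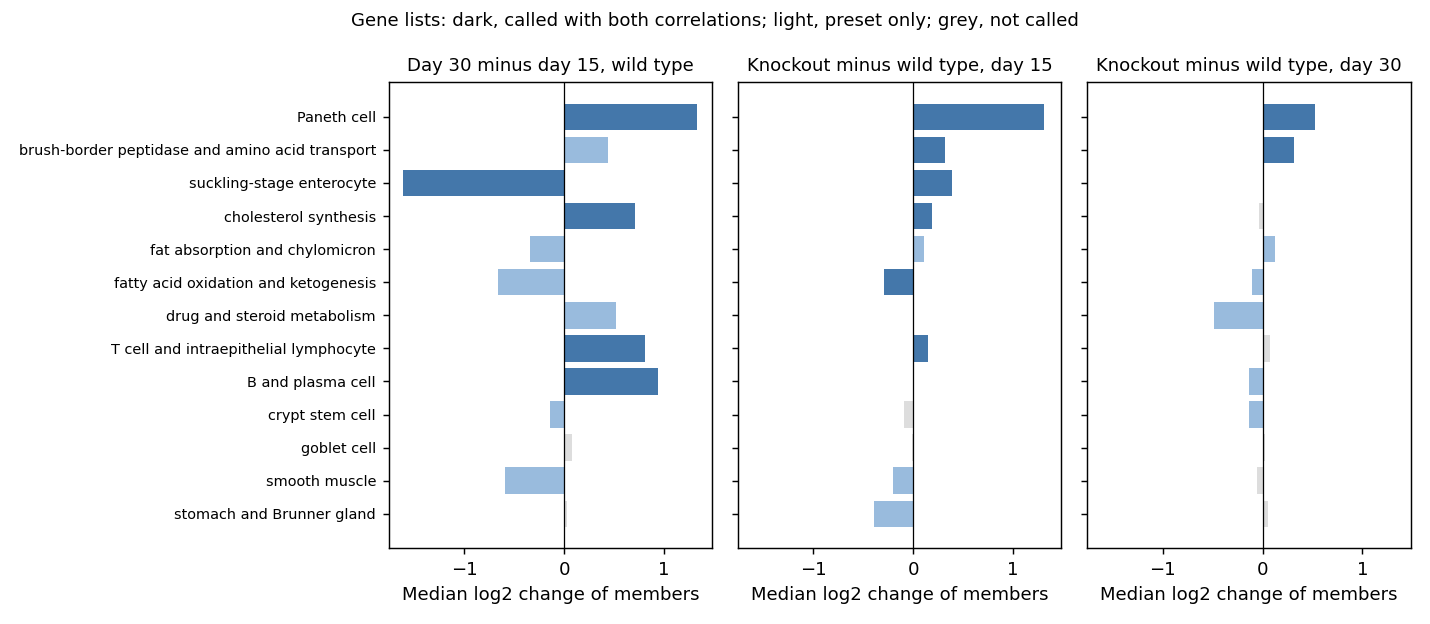
Median log2 change of the measured members of 13 gene lists, for age in wild type and for genotype at each age, on a shared horizontal axis; dark bars mark lists called with both the preset and the estimated inter-gene correlation, light bars the preset alone, and grey bars neither. Paneth cell genes had positive medians in each panel (1.33, 1.31 and 0.52), and fatty acid oxidation genes had negative ones (-0.66, -0.29 and -0.11).

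At day 15 the knockout duodenum had much less Tmprss15, which encodes enteropeptidase, the duodenal activator of trypsinogen (10.35 ± 0.13 in wild type, 6.10 ± 0.73 in knockout, SD, n = 3; log2 fold change -4.25, SE 0.27, limma adjusted p = 1.5e-06). The fatty acid hydroxylases Cyp4a31 (-3.92, SE 0.18) and Cyp4a10 (-3.55, SE 0.11) were also lower. The membrane transferrin-like gene Meltf (3.48, SE 0.12) and the peptidase gene Naaladl1 (3.25, SE 0.11) were higher. Paneth cell genes were higher, with a list median of 1.31, and 7 of 18 genes of fatty acid oxidation were lower.

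At that age 764 genes passed, with 360 higher and 404 lower in knockout, and 35 and 26 of these differed at least 2-fold. The other largest rises were those of Ifi202b (2.77), Mamdc4 (2.23), Prss3 (2.23), neurotensin (Nts, 1.89), the folate receptor Folr1 (1.84) and guanylin (Guca2a, 1.83), with SEs of 0.10 to 0.27. The other largest falls were those of alpha-fetoprotein (Afp, -2.45), the proton channel Otop3 (-2.07), Sult6b2 (-2.06), the bile salt pump Abcb11 (-1.93) and the glial marker S100b (-1.70), with SEs of 0.11 to 0.17. Sox10, another glial gene, averaged 7.38 in both genotypes at day 15, so the fall of S100b cannot be read as a loss of glia.

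Of 9 Paneth cell genes, 7 were higher over all genes and 8 adjusted over the list alone, with Defa24 at 1.67, Mmp7 at 1.37, Itln1 at 1.32, Ang4 at 1.31 and Lyz1 at 1.15 (list median 1.31, camera adjusted p = 2.0e-21, 0.014 with an estimated correlation). Defa24 belongs to a family of near-identical genes, so its value may include relatives. The phospholipase gene Pla2g2a, also among the 9 Paneth cell genes, was higher by 1.41. Of 18 fatty acid oxidation genes, 7 were lower over all genes and 14 adjusted over the list alone, including Acadm (-1.01), Ehhadh (-0.72) and Acaa2 (-0.52), and the list fell (median -0.29, camera adjusted p = 1.2e-16, 0.048 with an estimated correlation). That median was -0.17 with the smooth muscle mean as a covariate and -0.19 with the pancreas acinar mean, and the list was called in both fits with the preset correlation. Of 18 brush-border peptidase and amino acid transport genes, 8 were higher and 2 lower (11 and 2 adjusted over the list alone), with Xpnpep2 at 0.93 and Ace at 0.74 beside Naaladl1, and Tmprss15 among the lower (median 0.32, camera adjusted p = 1.3e-08, 0.048 with an estimated correlation).

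Suckling-stage genes were higher in knockout in 5 of 12 cases (7 adjusted over the list alone), among them Dab2 (0.91), Gusb (0.62) and Glb1 (0.56), and none was lower (median 0.39, camera adjusted p = 2.1e-08, 0.048 with an estimated correlation). Sucrase-isomaltase, a gene of the weaned gut, was higher too (Sis, 0.66, limma adjusted p = 0.0050), while the fructose transporter Slc2a5 was lower (-0.42, limma adjusted p = 0.048). Cholesterol synthesis genes rose in 4 of 18 cases over all genes and in 11 adjusted over the list alone, with Idi1 at 0.44 and Msmo1 at 0.41 (camera adjusted p = 3.8e-10, 0.048 with an estimated correlation). Of 17 T cell genes, Gzmb (0.73) and Cd7 (0.37) rose over all genes and 6 adjusted over the list alone (camera adjusted p = 3.4e-05, 0.023 with an estimated correlation). Among gut hormones, Glucagon (Gcg, 1.05), Gip (0.72) and Cck (0.61) rose with Nts, and the serotonin-synthesis gene Tph1 (-0.88), Ghrl (-0.42) and Sct (-0.31) fell, and that list was not called (camera adjusted p = 0.78). Of 74 calls of named genes at day 15, 39 ended with the smooth muscle mean as a covariate, among them those of Ang4, Acaa2, Glb1, Sis, Slc2a5, Idi1, Msmo1, Gzmb, Cd7, Gcg, Tph1, Ghrl, Sct and Lgr5 and, of the genes in the next paragraph, Muc6 and Myh11. In that fit Gcg was at 1.21 (SE 0.26) and no longer passed (limma adjusted p = 0.079). The stem cell marker Lgr5 was lower (-0.50, limma adjusted p = 0.0063).

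Transcripts of other tissues in the segment moved with genotype at day 15. Stomach and Brunner gland genes were lower, with Muc6 at -0.67, Gkn3 at -0.62 and Tff2 at -0.53 (3 of 13 over all genes, 4 adjusted over the list alone, list median -0.40, adjusted p = 0.017, or adjusted p = 0.43 with an estimated correlation). The smooth muscle list had a median of -0.21, with 2 of 12 members lower over all genes and 10 adjusted over the list alone (adjusted p = 1.6e-07, or adjusted p = 0.18 with an estimated correlation), with Myh11 at -0.31. The pancreas acinar list had a median of -0.43 with 0 of 14 members called over all genes, and 1 higher and 5 lower adjusted over the list alone (adjusted p = 0.0069, or adjusted p = 0.53 with an estimated correlation). The interferon list had a median of 0.40 with 0 of 15 members called (adjusted p = 0.0015, or adjusted p = 0.50 with an estimated correlation), and its mean per array ran from 8.80 to 10.46 within the knockout group alone. With the smooth muscle mean as a covariate the calls of the stomach and Brunner gland, interferon, antimicrobial, calcium uptake and proximal transcription factor lists ended and the pancreas acinar list turned (median 0.14, camera adjusted p = 0.033). The stomach mean ended those of the interferon, pancreas and calcium lists, the pancreas mean that of the stomach list, and the interferon mean those of the stomach and calcium lists. The count of 764 fell to 116 with the smooth muscle mean as a covariate, to 317 with the pancreas mean and to 379 with the stomach and Brunner gland mean, and it was 480 from the 6 day 15 arrays alone and 1218 with array weights. It was 505, 429 or 412 without wild type replicate 1, 2 or 3, and 340 or 445 without knockout replicate 2 or 3. Of the 37 lists, 16 were called with the preset correlation and 7 with an estimated one, and another split of the same 6 arrays called 15 with the preset.

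At day 30 Tmprss15 was again the gene most reduced in knockout (11.81 ± 0.09 in wild type, 7.79 ± 0.29 in knockout, SD, n = 3; log2 fold change -4.02, SE 0.27, limma adjusted p = 5.7e-06), followed by Otop3 (-2.93, SE 0.11). Naaladl1 (2.87, SE 0.11) and the gasdermin genes Gsdmc2 (2.54, SE 0.19) and Gsdmc4 (2.29, SE 0.15) were most raised. Of 9 Paneth cell genes 5 were higher, and of 18 brush-border peptidase and amino acid transport genes 9 were higher. Of 18 genes of drug and steroid metabolism 6 were lower, and the call of that list was lost with an estimated correlation (adjusted p = 0.15).

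In that comparison 395 genes passed, 207 higher and 188 lower, with 28 and 17 changed at least 2-fold. Other large rises were those of Bcl2l15 (2.29), Ppef1 (1.75), the amino acid transporter Slc6a14 (1.69), the citrate transporter Slc13a2 (1.65) and Guca2a (1.64), with SEs of 0.10 to 0.39. Other large falls were those of Nat8f2 (-2.002), Afp (-1.88), Cyp2c55 (-1.88) and the carboxylesterases Ces2a (-1.52) and Ces2g (-1.27), with SEs of 0.10 to 0.33. The gasdermin C and carboxylesterase genes have close relatives, and their values may include these.

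Of 18 brush-border peptidase and amino acid transport genes, 9 were higher over all genes and 13 adjusted over the list alone, including Xpnpep2 (1.07) and Dpp4 (0.59), and only Tmprss15 was lower (median 0.31, camera adjusted p = 9.9e-14, 0.036 with an estimated correlation). Of 9 Paneth cell genes, 5 were higher over all genes and 7 adjusted over the list alone, with Mmp7 at 0.89, Itln1 at 0.62 and Spink4 at 0.52 (median 0.52, camera adjusted p = 4.9e-13, 0.036 with an estimated correlation). Pla2g2a, another of these 9 genes, was higher by 1.05. Among 9 calcium uptake genes, the tight junction gene Cldn2 was lower (-1.06, limma adjusted p = 9.4e-06) and no other passed over all genes, while 2 passed adjusted over the list alone, and the list fell (median -0.19, camera adjusted p = 1.3e-04, 0.036 with an estimated correlation).

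Of 18 drug and steroid metabolism genes, 6 were lower (8 lower and 1 higher adjusted over the list alone), among them the transporters Abcb1a (-0.84) and Abcc2 (-0.63) and the glucuronosyltransferase Ugt2b5 (-0.92), and the list's adjusted p was 5.4e-10, or adjusted p = 0.15 with an estimated correlation. Fat absorption genes were higher in 4 of 21 cases (9 adjusted over the list alone), with Gpat3 at 0.43, Cd36 at 0.38 and Dgat2 at 0.35 (adjusted p = 1.0e-09, or adjusted p = 0.10 with an estimated correlation). Among 18 fatty acid oxidation genes, Cyp4a10 (-0.82) and Acaa2 (-0.79) were lower, and 4 adjusted over the list alone (adjusted p = 1.9e-05, or adjusted p = 0.26 with an estimated correlation). Glucagon (Gcg, 1.57), Nts (0.90), Gip (0.47) and Cck (0.38) were higher, and Ghrl (-0.61) and Sct (-0.32) lower. The glucocorticoid-responsive gene Fkbp5 was higher by 1.11, lactase (Lct) by 0.71, and the stem cell genes Lgr5 (-0.43) and Rnf43 (-0.41) were lower. Gkn3 was lower (-0.33), and the smooth muscle list was not called (median -0.06, camera adjusted p = 0.25). The pancreas acinar list was lower with 0 of 14 members called by either adjustment (median -0.29, adjusted p = 0.0011, or adjusted p = 0.62 with an estimated correlation), and Ctrl (-0.71), Pnliprp1 (-0.55) and Cela1 (-0.53) did not pass. Xist had a log2 fold change of 0.78 and Kdm5d of -0.60 at day 30, neither of which passed (limma adjusted p = 0.37 and 0.39), against -0.25 and 0.33 at day 15.

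Of 46 calls of named genes, 10 ended with the pancreas acinar mean as a covariate, among them those of Ppef1, Lct, Lgr5, Cd36 and Sct. The count of 395 was 230 with the pancreas acinar mean as a covariate, 237 from the 6 day 30 arrays alone and 596 with an intensity trend in the variance prior, and it was 260 or 218 without wild type replicate 2 or 3 and 225 without knockout replicate 1. Of 37 lists, 15 were called with the preset correlation and 3 with an estimated one, and another split of the same arrays called 12 with the preset.

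The genotype effects at the 2 ages overlapped in part. There were 189 genes called at both ages, 97 higher at both, 90 lower at both and 2 in opposite directions, where independent lists of those sizes would share 3.74 higher and 3.81 lower. Across genes, which are not independent replicates, the effects correlated with Pearson r = 0.42 and Spearman rho = 0.23, and the ages share no arrays. Both calls of a gene use the same variance estimate, which can raise the overlap above that of independent lists. It would raise calls in opposite directions as much, though, and 2 genes were opposite against 97 higher and 90 lower at both ages. That agreement in direction argues against the shared variance estimate as the whole source of the overlap. Averaged over both ages, 1064 genes passed (494 higher, 570 lower), with the largest falls for Tmprss15 (-4.13), Otop3 (-2.50), Cyp4a31 (-2.32), Cyp4a10 (-2.18) and Afp (-2.16) and the largest rises for Naaladl1 (3.06), Bcl2l15 (1.78), Prss3 (1.76), Guca2a (1.73) and Gsdmc2 (1.72). Of 87 calls of named genes in that average, 43 ended with the smooth muscle mean as a covariate and 32 with the pancreas acinar mean. The count of 1064 was 307 with the smooth muscle mean as a covariate, 436 with the pancreas acinar mean, and 668 without day 15 knockout replicate 2. Of the lists, 18 were called with the preset correlation and 4 with an estimated one.

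**Figure D3:**
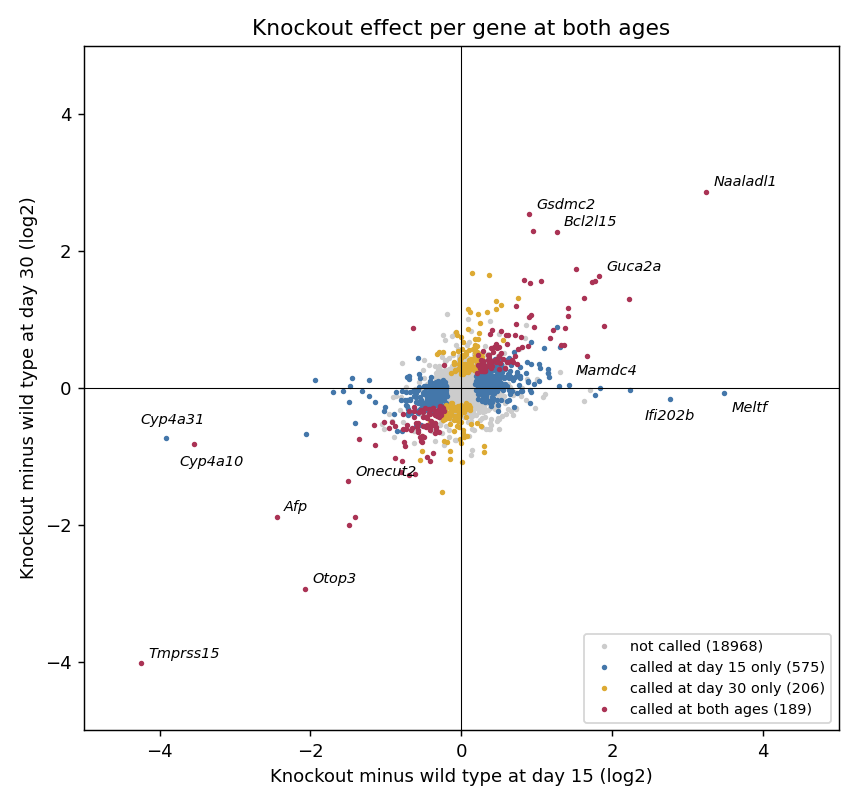
Knockout minus wild type log2 difference of each of the 19938 genes at day 15 (horizontal) and at day 30 (vertical), coloured by the age at which the gene was called. Tmprss15 (-4.25 and -4.02) and Naaladl1 (3.25 and 2.87) lie far from zero on both axes, while Meltf differed by 3.48 at day 15.

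The genotype effect differed between ages for 91 genes, 46 with a higher and 45 with a lower effect at day 30. Meltf (difference -3.56, SE 0.17), Ifi202b (-2.93, SE 0.38), Mamdc4 (-2.25, SE 0.18), Folr1 (-1.84, SE 0.23) and Aoc1 (-1.38, SE 0.18) were raised in knockout at day 15 and not at day 30. Cyp4a10 (2.73, SE 0.16) fell more at day 15 than at day 30, while Cyp4a31 (3.19, SE 0.25), Abcb11 (2.05, SE 0.17) and S100b (1.65, SE 0.16) fell at day 15 and had effects of -0.73, 0.11 and -0.05 at day 30 that did not pass, and Gsdmc2 was raised more at day 30 (1.65, SE 0.26). At day 30 the wild type means of Cyp4a31, Cyp4a10, Abcb11 and S100b were 5.36, 6.73, 5.63 and 6.21, while olfactory and vomeronasal receptor genes, taken as background, averaged 4.78 over the arrays. For Cyp4a31, Cyp4a10 and Abcb11 a fall as large as at day 15 could not have been measured there, so the sizes of their differences are set in part by the floor. Single genes read below that background mean, such as Saa1 at 4.10 in day 15 knockout. The part of the floor in the difference of S100b is therefore unclear. Among Paneth genes Defa24 (-1.20), Lyz1 (-0.92) and Itln1 (-0.70) had smaller knockout effects at day 30 (3 of 9, and 4 adjusted over the list alone), and among fatty acid oxidation genes the falls of Acadm (0.74) and Ehhadh (0.55) were smaller at day 30. Lyz1 averaged 13.97 in wild type and 14.20 in knockout at day 30, bright enough for saturation to shrink its effect, which was not tested. Defa24 and Itln1 were less bright, each at 12.08 in day 30 wild type. Of 37 lists, 10 were called with the preset correlation and 0 with an estimated one by camera, and 28 of 100 regroupings of genotype within age gave 10 or more with the preset. With the smooth muscle mean as a covariate 8 of 20 calls of named genes ended, those of Ifi202b, Gsdmc2, Acadm and Ehhadh among them. The count of 91 was 35 with the smooth muscle mean as a covariate, 177 with an intensity trend, 159 above the median intensity and 155 with array weights. It was 47, 60, 49, 56 or 47 without day 15 wild type replicate 2 or 3, day 15 knockout replicate 2 or 3, or day 30 wild type replicate 3.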

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

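The tests of explanations in this part were chosen after the results were seen, and the counts over other splits of the arrays were planned. The results listed here differed between the ages by the test of the difference itself, the knockout effect at day 30 minus that at day 15. In groups of 3 no array was tested as standing apart from its group.

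That difference passed for 91 genes, and 3 of 100 regroupings of genotype within age, the real one included, gave as many, the highest other giving 138. The regroupings also break up the genotype effect shared by both ages, which widens the spread within groups. They therefore do not test the difference alone, and that share cannot exclude chance for it. What set the regroupings with high counts was not analysed here. Meltf (-3.56), Ifi202b (-2.93), Mamdc4 (-2.25), Folr1 (-1.84), Aoc1 (-1.38), Lyz1 (-0.92), Dab2 (-0.94), Idi1 (-0.49) and Sc5d (-0.40) had positive knockout effects at day 15 and effects that did not pass at day 30. Defa24 (-1.20) and Itln1 (-0.70) had smaller positive effects at day 30. Lyz1 averaged 13.97 in wild type and 14.20 in knockout at day 30, bright enough for saturation to shrink its effect, which was not tested. Cyp4a31 (3.19), Cyp4a10 (2.73), Abcb11 (2.05), S100b (1.65), Acadm (0.735) and Ehhadh (0.549) had negative effects at day 15 that were nearer 0 at day 30. Wild type Cyp4a31, Cyp4a10 and Abcb11 were at 5.36, 6.73 and 5.63 at day 30, too near the receptor background of 4.78 for a fall as large as at day 15. Wild type S100b was at 6.21, where the floor may shrink such a fall, though single genes read below that background mean. Gsdmc2 had the larger rise at day 30 (1.65). Lrat (-0.80) and Abcb1a (-1.14) were lower in knockout at day 30, with day 15 effects that did not pass.

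Of the lists, 10 differed between the ages with the preset correlation and 0 with an estimated one. Chance cannot be excluded for that count, since 28 of 100 regroupings gave 10 or more and the highest other gave 19. The list medians of the difference were -0.227 for suckling-stage genes, -0.241 for cholesterol synthesis, 0.205 for fatty acid oxidation, -0.073 for proximal transcription factors, -0.697 for Paneth cells, -0.068 for T cells, -0.778 for the interferon response, 0.201 for smooth muscle, -0.274 for drug and steroid metabolism and 0.336 for the glucocorticoid response.

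For genotype averaged over both ages, 1 of 100 regroupings, the real one, gave 1064 genes (highest other 163), so chance can be excluded for the gene count. For lists, 3 of 100 gave 18 (highest other 18). A regrouping that called 0 genes gave 18 lists, and 4 lists were called with an estimated correlation, so chance is not excluded for the list count. The 10 splits of 3 against 3 arrays are too few for a share under 0.05. Over them, the real gene counts and the highest others were 5849 and 0 for age in wild type, 6178 and 0 for age in knockout, 764 and 1 for genotype at day 15, and 395 and 0 at day 30. The list counts were 18 and 18 (2 of 10 splits), 20 and 14, 16 and 15, and 15 and 12 (each 1 of 10). Wrong splits that called at most 1 gene thus called up to 18 lists with the preset correlation.

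Tmprss15, Otop3 and Afp were lower and Naaladl1, Guca2a, Gcg and Nts higher in knockout at both ages, although the day 15 call of Gcg ended with the smooth muscle covariate, where its effect went from 1.05 (SE 0.16) to 1.21 (SE 0.26, limma adjusted p = 0.079) and the wider SE ended the call. Among bright stomach and Brunner gland genes the lowest day 30 effect less 2 SE was -0.617, far from the -4.02 of Tmprss15. Knockout segments cut further from the stomach would be argued against if these genes dropped along the duodenum as steeply as Tmprss15. That was not measured here, so the test cannot decide. A shift of position, in part or as the whole cause, stays open, and Muc6, Tff2 and Gkn3 were lower at day 15. A shift towards ileal expression stays open, since Fabp6 and Slc10a2 (highest effect plus 2 SE 0.332) had means of 4.86 and 6.10, at or near the receptor background of 4.78, where such a test excludes nothing. A shift towards jejunum and a direct effect of losing Onecut2 were not tested and remain open.

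Fatty acid oxidation genes were lower in knockout at day 15. A lower share of enterocytes, as the whole cause, is argued against by the fat absorption list. It was assumed, not measured, that a lower share would lower its members by about as much. Its median of 0.103 lay 0.395 above that of the oxidation list, more than its members' SD of 0.275. Its members moved both ways, with Abcg5 (-0.57) and Abcg8 (-0.42) lower and Cd36 (0.68) and Gpat3 (0.55) higher, and its own call was lost with an estimated correlation (adjusted p = 0.25). The oxidation median went from -0.292 to -0.174, -0.192, -0.2 and -0.232 with the smooth muscle, pancreas acinar, stomach and interferon means as covariates. The oxidation list stayed called in each fit with the preset correlation. A part played by tissue composition stays open. Earlier maturation of the epithelium as a whole, with no other change, is argued against by the suckling-stage list, which falls with age and was higher in knockout (median 0.386). Whether a shift of position, left open above, also moves that list was not tested. Earlier maturation beside such a shift is therefore not excluded. Earlier maturation of a part stays open, as do food intake, which was not tested, and a genotype effect, since the Paneth, cholesterol synthesis and T cell lists, which rise with age, were higher, and the smooth muscle list, which falls, was lower (its call lost with an estimated correlation, adjusted p = 0.18).

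Paneth cell genes were higher in knockout at day 15. As the whole cause, more crypt tissue is argued against by the crypt stem cell list, whose highest effect plus 2 SE was 0.34, and less muscle by the goblet list, whose median plus interquartile range was 0.172, both far below the Paneth median of 1.31. Lgr5 of the crypt list was itself lower in knockout (-0.50), so more crypt tissue as a part of the cause is not excluded. The smooth muscle mean per array was lower in knockout (10.33 to 10.51) than in wild type (10.60 to 10.71). With that mean as a covariate the Paneth median was 1.285. Earlier appearance of Paneth cells cannot be told apart from a lasting difference, since the list's difference between ages was -0.697 with adjusted p = 0.13 under an estimated correlation, and the list was also called higher at day 30 (median 0.52).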

How the results depend on the processing

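The fits without 4 arrays and with covariates were chosen after seeing the data, and the other alternatives were planned. Genes differing by genotype at day 15 numbered 764, and 480 from the day 15 arrays alone, 1218 with array weights, and 379, 317 and 116 with the stomach and Brunner gland, pancreas acinar and smooth muscle means as covariates. At day 30 they numbered 395, and 596 with an intensity trend, 237 from the day 30 arrays alone and 230 with the pancreas mean. The difference between ages counted 91 genes, and 177 with the trend, 159 with the dim filter at the median, 155 with array weights and 35 with the smooth muscle mean. The averaged effect counted 1064, and 436 with the pancreas mean and 307 with the smooth muscle mean. A covariate that differs between genotypes can take up part of the genotype effect and can widen its SE. With the smooth muscle mean, the day 15 effect of Gcg went from 1.053 (SE 0.156) to 1.211 (SE 0.263). That of Tmprss15 went from -4.248 (SE 0.266) to -4.015 (SE 0.45). In both genes the SE widened while the effect stayed near its size. They were chosen from genes that differed at both ages and do not stand for all 39 named calls that ended at day 15. Elsewhere effects shrank, as the median of the fatty acid oxidation list went from -0.292 to -0.174 in that fit. Beyond these shifts of effect and SE and the fewer arrays in a fit, the cause of the changed counts was not tested.

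Leaving out each array in turn gave 340 to 782 genes at day 15, 218 to 420 at day 30, 47 to 123 for the difference between ages and 668 to 976 for the averaged effect. At day 15 the count was 505, 429 and 412 without wild type replicates 1, 2 and 3, and 340 and 445 without knockout replicates 2 and 3. At day 30 it was 260 and 218 without wild type replicates 2 and 3 and 225 without knockout replicate 1. For the difference between ages it was 47 and 60 without day 15 wild type replicates 2 and 3, 49 and 56 without day 15 knockout replicates 2 and 3, and 47 without day 30 wild type replicate 3. Without day 15 knockout replicate 2 the averaged effect counted 668. The age counts stayed between 4561 and 6175 in wild type and between 4990 and 6258 in knockout.

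With an estimated correlation the lists called were 5 and 3 for age in wild type and knockout, 7 and 3 for genotype at days 15 and 30, 0 for the difference between ages and 4 for the averaged effect. With the smooth muscle mean as a covariate the pancreas acinar list turned, with a median of 0.141 at day 15 and, by its test, at -0.044 in the averaged effect. The maturation difference at day 15 was -0.684 with the median of the list members, and at day 30 it lay between -0.07 and 0.019 with an array left out, on both sides of 0.

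Replicate numbers did not pair the arrays throughout, since same-numbered arrays had correlations of -0.252 to 0.359, with 7 of 18 above 0.1, and 5 of 12 arrays correlated best with their own number. The first component within groups held 29.9% of that variance and was highest on replicate 1, but on replicate 3 of the day 30 knockout. That array had correlations of 0.341, 0.373 and 0.075 with replicate 1 of day 15 wild type, day 30 wild type and day 15 knockout. A block by number does not capture such structure. With the number as a block the gene counts were 5726, 6039, 611, 331, 80 and 898, and the list counts 17, 20, 16, 16, 10 and 20, in the order age in wild type and knockout, genotype at days 15 and 30, difference, average. Without the 4 arrays highest on the first component within groups, the gene counts were 5427, 5342, 601, 290, 100 and 809. Of 364 age calls of named genes, 323 were kept in each alternative run, which included no covariates. Of 227 genotype calls, 118 were kept in each alternative and 125 with each of the 4 covariates (35 of 74 at day 15, 36 of 46 at day 30, 12 of 20 for the difference and 42 of 87 for the average), and 0 reversed. The smooth muscle mean ended 39, 3, 8 and 43 of these, the pancreas mean 21, 10, 3 and 32, the stomach mean 20, 1, 3 and 23, and the interferon mean 13, 4, 4 and 3. Of list calls, 8 of 38 for age and 14 of 59 for genotype were kept in each, and 44 of the 59 with each covariate. Other normalizations moved the share of higher calls by under 10 points.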

Other observations

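The Reactome sets were planned as a screen, and all sentences on them describe calls with the preset correlation; with an estimated correlation 0 sets were called by camera in any comparison. Of 885 sets, 90 were called for age in wild type and 25 for genotype at day 15. Genes of the extracellular matrix were lower at day 30 in wild type, with 27 of 35 elastic fibre genes and 41 of 62 proteoglycan genes lower (adjusted p = 0.27 for both with an estimated correlation), beside the fall of the smooth muscle list. At day 15 the knockout had 9 of 118 genes of the citric acid cycle and respiratory electron transport lower and 1 higher (median -0.12, adjusted p = 0.99 with an estimated correlation). At day 30, 7 of 33 amino acid transport genes were higher in knockout and 0 lower (adjusted p = 0.46 with an estimated correlation).

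Among neighbours of Onecut2 on chromosome 18, Lman1 (0.53) and Nars (0.19) were higher and St8sia3 lower (-0.53) in knockout at day 15, and the list was not called (camera adjusted p = 0.13). At day 30 Lman1 was higher (0.83), St8sia3 (-0.24) and Nars (0.10) did not pass, and the list was not called (camera adjusted p = 0.36).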
